A study of Mus musculus with 6 samples.

How the data were processed

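Hippocampal RNA of 6 wild-type mouse samples, 3 per group, was made into stranded mRNA libraries and sequenced as 150 bp paired-end reads, on an Illumina NovaSeq instrument, per the labels' protocols. Per the labels' protocols the reads were trimmed with fastp 0.20.0, aligned with HISAT2 2.1.0 and counted per gene with featureCounts 2.0.1. DESeq2 1.28.0 is named in the submitters' processing notes. The genome build, the annotation version and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and genes that overlap or have near-identical copies may share reads. Groups were taken from the treatment label of each sample.

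The deposited workbook holds 2 sheets with identical values, of which one was used. It holds the authors' comparison of the groups. Its mean count column is a signal, the mean over the libraries of counts divided by size factors, as the deposited column name and the values show. The deposited log2 fold change and its error are on the log2 scale and were shrunken toward 0 by the authors, as the values show. The deposited p-value and adjusted p-value columns are the authors' own, and the adjusted p is blank for every gene with a mean under 5.67. Which treatment is the numerator is not stated, and the type of test behind the p-values is not given in the sources used here. Values of single libraries were not used here, so the quasi-likelihood test planned before the data were examined gave way to the fallback fixed with it, the authors' adjusted p at 0.05. A set test on the authors' z values took the place of one on counts. The deposited symbols were used as gene names, and 55144 of the 55471 gene IDs matched a reference table of mouse gene names. Of 30480 genes with counts, 3 have no p (Alb, Ahsg and Pcdhac2).

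A signed z was computed as the normal quantile of the p-value with the sign of the deposited fold change. The unshrunken fold change and its standard error were back-calculated by assuming that the deposited value is a peak of the product of a normal likelihood and a Cauchy prior. The prior's scale, 0.0357, was taken from genes with the lowest counts. This shape of the prior is inferred from the values. As a check, among 255 genes with a deposited fold change above 0.3 in size, the z implied by the deposited error was 1.001 ± 0.004 (SD) times the z from the p-value. That check depends little on the prior's scale. Where the deposited value lies near 0, the back-calculated value rests on the assumed prior and its scale. For 30 such genes with z above 3 in size, a second estimate of the error was 0.94 times the first (median, quartiles 0.85 and 0.96). This second estimate used the deposited error and the same prior. The back-calculation gave a value for 18315 of the 18603 tested genes and for all 61 called genes, and for 400 of 400 simulated genes it came within 1%. The simulated genes were made with the same prior and scale, so they check the calculation and not the assumed prior. For genes with z near 0 the value is poorly determined. The number of libraries was checked on 5748 mean counts below 0.6: all (100.0%) were whole combinations of the 6 steps within 1e-06. These steps cannot be tied to sample names.

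The 45 gene lists were fixed before the data were examined, and 7 more were added afterwards. Lists with at least 5 tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on z, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 43 lists (the sex-linked genes served as a check only). In 100 simulated tables of 18603 genes with a shift of 1.5 in z in a single list, that list was found in 99 tables and 4 other lists were called in all. The simulated genes were drawn independently, so this check cannot show how often lists of correlated members are called. The count adjusted over the list alone used Benjamini-Hochberg adjustment within each list. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

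Genes were named by a rule fixed before the data were examined: those with an adjusted p under 0.05, a mean of at least 1 CPM and an established symbol, up to 10 of the largest deposited fold changes per direction, and up to 4 members with the smallest p per list. The rule's further condition, that the libraries of one group all lie above those of the other, was not applied, since it needs values per library. Some genes that the rule selects are not reported here. The rule left out 4 called genes, Capn11, Scgb3a1, Gm2446 and B230206H07Rik. Of the other settings listed before the data were examined, an adjusted p under 0.1, a minimum of 2-fold and camera on ranks were run. Other normalizations, filters and count models, leaving out each library, an estimated correlation, fry and other splits of the samples need values per library and were not run. Alternatives added after seeing the data are named with their values in the closing section. GC content and transcript length were taken from a mouse reference annotation for 18579 tested genes (99.87%); with the mean count they accounted for 3.45% of the variance of z. The correlation of z across genes was -0.019 with GC content and 0.131 with length; genes are not independent replicates.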

Results

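RNA of the mouse hippocampus was sequenced 24 hours after cerebral ischemia and reperfusion, a model of stroke in which blood flow to the brain is stopped and then restored. The 6 wild-type samples fall into 2 groups, 3 treated with saline and 3 treated with Visudyne. Visudyne is a preparation of the photosensitizer verteporfin, and the series uses it to ablate the lymphatic vessels of the meninges, which drain fluid and immune cells from the brain's coverings toward the cervical lymph nodes. The comparison asks how hippocampal gene expression after stroke differs between animals with and without this treatment. The values used here are the authors' comparison of the groups, a mean normalized read count, a log2 fold change with its error and p-values per gene, so values of single libraries were not analysed here. The labels do not say whether each sample came from its own animal, and p-values then measure only the spread between these samples, which may be technical.

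The deposited columns do not state which treatment is the numerator of the fold change. Directions are therefore given as the sign of the deposited value. A positive value would mean higher expression in the Visudyne group if the groups had been ordered alphabetically, the default of the tool the authors used, but the files do not state this order. The authors' deposited table lists 55471 genes, of which 30480 have a mean count above 0 and 18603 have an adjusted p. The normalized mean counts sum to 25011655, and the median tested gene has a mean of 334 normalized counts. Library totals were not used here, but the smallest mean counts fall on 6 steps, those of 1 read in 1 library, and these steps correspond to library size factors from 0.584 to 1.517, a 2.6-fold range in depth. The 3 steps on the positive side of the fold change gave size factors of 1.197, 1.055 and 0.584, and the 3 on the negative side gave 1.517, 1.223 and 0.754.

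Genes of meningeal fibroblasts were among those with the largest positive values, and genes of microglia and of myelin-forming oligodendrocytes among those with the largest negative values. In the authors' deposited table, 61 of the 18603 tested genes have an adjusted p under 0.05, 34 with a positive and 27 with a negative fold change. At an unadjusted p under 0.05 there are 1267 genes, 729 positive and 538 negative, where 930 would be called by chance. The SD of the z values over all tested genes is 1.088, and dividing z by this SD left 19 of the 61 genes past the threshold, 12 positive and 7 negative. The deposited fold changes are shrunken toward 0. For 56 of the 61 genes they lie between 0.46 and 2.35 in size on the log2 scale, and for the other 5 they lie within 0.03 of 0.

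On the positive side, the largest value among the genes named by rule belongs to Fmod (ENSMUSG00000041559), which encodes fibromodulin, a collagen-binding proteoglycan. Its log2 fold change is 1.89 ± 0.41 in the authors' deposited table (deposited error, adjusted p = 0.000579). Bmp3, a member of the TGF-beta superfamily, follows in the authors' deposited table with 1.62 ± 0.39 (adjusted p = 0.00244). The authors' deposited table gives 1.46 ± 0.47 for Slc22a6, an organic anion transporter (adjusted p = 0.0261), and 1.38 ± 0.35 for Slc6a20a, a proline transporter (adjusted p = 0.004). Ccn2 (ENSMUSG00000019997), a secreted matrix-associated protein, and Cplx3 (ENSMUSG00000039714), a complexin of synaptic vesicle release, mark layer 6b of the cortex, and both have an adjusted p of 0.000199 in the authors' deposited table, with log2 fold changes of 1.45 ± 0.29 and 1.33 ± 0.27. Nxph3, a secreted ligand of neurexins, has 1.23 ± 0.29 in the authors' deposited table (adjusted p = 0.00244). The remaining named genes on this side in the authors' deposited table are Fermt1, an integrin activator, with 1.40 ± 0.47 (adjusted p = 0.0338), Sphk1, a sphingosine kinase, with 1.25 ± 0.40 (adjusted p = 0.0252), and Coch, an extracellular matrix protein, with 1.20 ± 0.37 (adjusted p = 0.0231). With z divided by its SD the adjusted p was 0.0983 for Slc22a6, 0.119 for Fermt1, 0.0965 for Sphk1 and 0.093 for Coch, which ends these calls. Fermt1 also lost its call over all genes with a p (adjusted p = 0.0554), and Fermt1 and Sphk1 with z corrected for GC content, length and mean count (adjusted p = 0.0757 and 0.0705).

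On the negative side, microglial and immune genes come first. Ly86 (ENSMUSG00000021423), a secreted partner of a Toll-like receptor homologue, has a log2 fold change of -1.58 ± 0.31 in the authors' deposited table (adjusted p = 0.000199). The microglial gene Fcrls has -1.26 ± 0.28 in the authors' deposited table (adjusted p = 0.00112). Pycard, the adaptor protein of inflammasomes, has -1.05 ± 0.30 in the authors' deposited table (adjusted p = 0.0158), and the alarmin Il33 has -0.84 ± 0.26 (adjusted p = 0.0244). Among oligodendrocyte genes, the authors' deposited table gives -0.89 ± 0.22 for the cytoskeletal gene Ermn (adjusted p = 0.00282) and -0.83 ± 0.25 for the transferrin gene Trf (adjusted p = 0.0191). Serpinb1a, a protease inhibitor, has -0.99 ± 0.34 (adjusted p = 0.038) and Abca8a, a lipid transporter, -0.90 ± 0.29 (adjusted p = 0.0295) in the authors' deposited table. With z divided by its SD the calls of Pycard (adjusted p = 0.0702), Il33 (0.0947), Trf (0.0798), Serpinb1a (0.131) and Abca8a (0.108) were lost. Serpinb1a also lost its call over all genes with a p (adjusted p = 0.0623) and with corrected z (adjusted p = 0.0625).

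**Figure D1:**
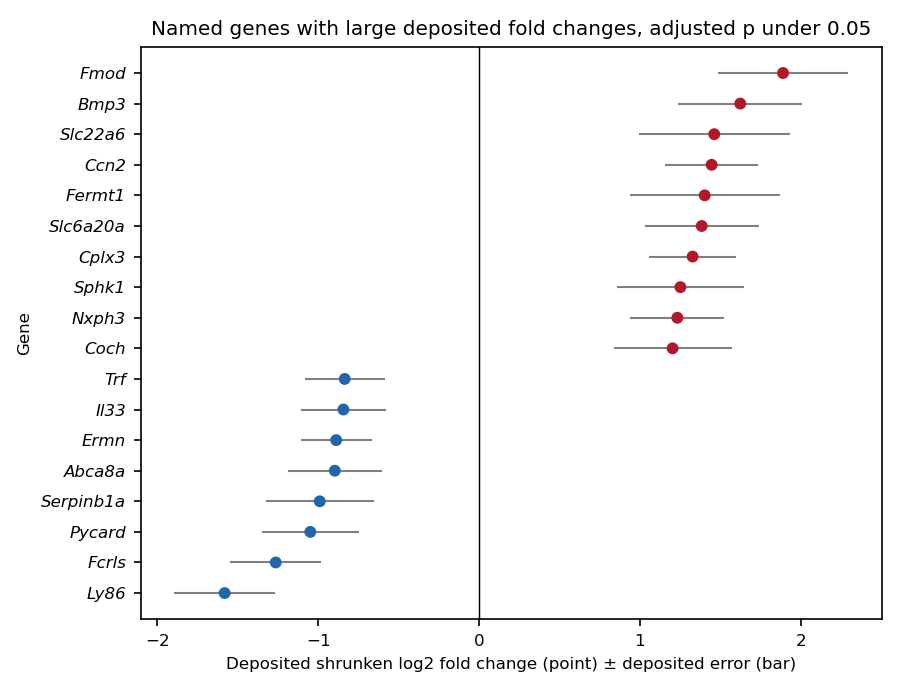
Deposited log2 fold changes (x axis, shrunken, log2 units) of 10 genes with large positive (red) and 8 with large negative (blue) values among those with an adjusted p under 0.05, as named by rule and reported here; bars show the deposited error. Values run from -1.58 for Ly86 to 1.89 for Fmod in the authors' deposited table.

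**Figure D2:**
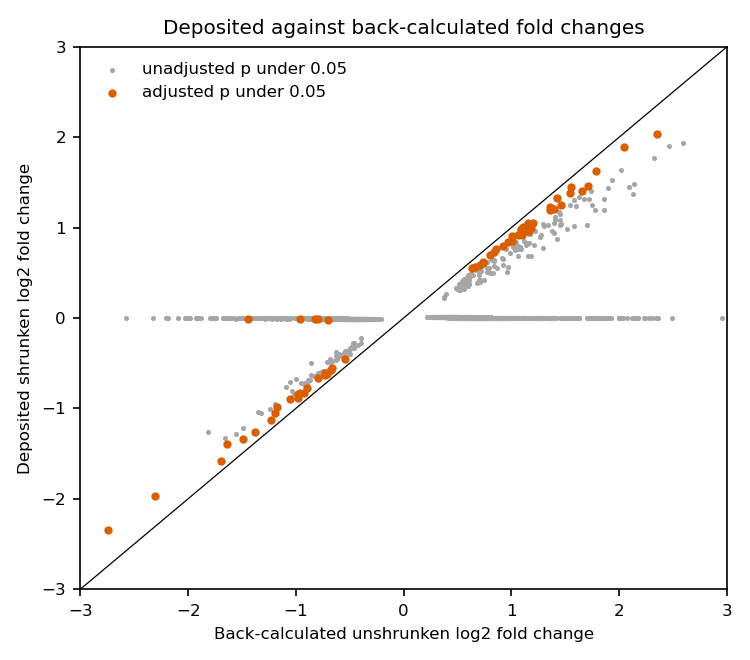
Deposited shrunken log2 fold change (y axis) against the back-calculated unshrunken value (x axis), both in log2 units, for genes with an unadjusted p under 0.05 (grey) and an adjusted p under 0.05 (orange); the line marks equal values and 1243 of 1248 genes lie within the plotted range. Of these 1248 genes 1000 have a deposited value within 0.03 of 0.

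Because the deposited fold changes of most genes are pulled close to 0, the values of gene list members below are unshrunken log2 fold changes back-calculated from the deposited fold change, its error and the p-value, each with its standard error. Where the deposited value lies near 0, both the value and its standard error rest on the assumed prior and its scale. Each of the 43 lists with at least 5 tested members was compared with all other tested genes by the camera test on z values, with a preset correlation of 0.01 between members, and p-values were adjusted over the lists. Of these lists, 21 passed an adjusted p of 0.05, 8 on the positive and 13 on the negative side. Of the called list members outside the largest fold changes, Slc6a13, Dcn, C4b, Fgfr3, Reln and Mfsd2a lost their calls with z divided by its SD (adjusted p from 0.0702 for Reln to 0.158 for Dcn). The calls of Slc6a13, C4b, Fgfr3 and Dcn were also lost over all genes with a p (adjusted p from 0.063 to 0.0793), and those of Fgfr3 and Dcn with corrected z (adjusted p = 0.0743 and 0.0757). The correlation between members could not be estimated without values per library. With a preset correlation of 0.2, 7 lists passed, and the adjusted p at that setting is given for each list whose call it ends.

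Oligodendrocyte genes were negative as a group. Of 16 tested members 15 had a negative value, with a median log2 fold change of -0.37 (adjusted p = 1.77e-13 by camera). Ermn and Trf passed the threshold over all genes, and 7 members passed adjusted over the list alone. Opalin, a marker of mature oligodendrocytes, had -1.02 ± 0.27 and Ugt8a, an enzyme of myelin lipid synthesis, -1.22 ± 0.33. The abundant myelin gene Mbp, looked at after its value was seen, had -0.19 ± 0.15. Of 10 genes of oligodendrocyte precursors 8 were positive, with a median of 0.28 (camera adjusted p = 0.0459); no member passed over all genes, and 1 positive and 1 negative member passed adjusted over the list alone. Pdgfra, the growth factor receptor of precursors, had 0.65 ± 0.24, Bmp4 had 0.90 ± 0.38 and the lineage regulator Sox10 had -0.46 ± 0.14. This list's camera adjusted p was 0.103 with a correlation of 0.05, 0.332 with 0.2 and 0.0503 over genes with a mean of at least 1 CPM. Negative values of oligodendrocyte genes came together with positive values of meningeal and cortical genes, given below.

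Homeostatic microglia genes were negative in all 14 tested members, with a median log2 fold change of -0.37 (camera adjusted p = 5.26e-13). Fcrls and Itgam, an integrin of myeloid cells, passed over all genes, and 7 members passed adjusted over the list alone. Aif1, which encodes the microglial marker Iba1, had -1.18 ± 0.38 and Tmem119 had -0.60 ± 0.22. Genes of microglial activation were negative in 13 of 19 members with a median of -0.32 (camera adjusted p = 0.00459), none past the threshold over all genes and 3 adjusted over the list alone. The lipid-sensing receptor Trem2 had -0.65 ± 0.18, its signalling partner Tyrobp -0.51 ± 0.17 and lipoprotein lipase Lpl -0.68 ± 0.22. The adjusted p of the activation list was 0.288 with a correlation of 0.2.

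Inflammatory gene lists lay on the same negative side. Whether they moved independently of the microglia lists was not tested. Cytokines and chemokines had a median log2 fold change of -0.76, with 12 of 15 tested members negative (camera adjusted p = 0.000209) and no member past the threshold over all genes or adjusted over the list alone. Cxcl10, an interferon-induced chemokine, had -1.68 ± 0.64 and Ccl2, which recruits monocytes, -1.42 ± 0.58; their mean counts are low, 20.1 and 23.1 in the authors' deposited table. Genes of NF-kappaB and Toll-like receptor signalling were negative in 16 of 20 members, with a median of -0.27 (camera adjusted p = 0.00141), of which Pycard passed over all genes and adjusted over the list alone. Il1r1, the interleukin-1 receptor, had -0.48 ± 0.17, while Tlr7 had 0.63 ± 0.30. Interferon-stimulated genes were negative in 15 of 20 members with a median of -0.41 (camera adjusted p = 0.000238), none past the threshold over all genes and 1 adjusted over the list alone. Gbp2 had -1.35 ± 0.40 and Irf9, a transcription factor of interferon signalling, -0.70 ± 0.26. With a correlation of 0.2 the adjusted p of these lists was 0.106 for cytokines, 0.222 for NF-kappaB signalling and 0.155 for interferon-stimulated genes.

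Reactive astrocyte genes were negative in 15 of 22 members with a median log2 fold change of -0.48 (camera adjusted p = 0.000383 and 0.18 with a correlation of 0.2). Its called member over all genes, Sphk1, is positive; adjusted over the list alone 7 members passed on the negative and 2 on the positive side. Serpina3n, a protease inhibitor induced in reactive astrocytes, had -0.51 ± 0.16 and Ggta1 -0.81 ± 0.24. General astrocyte genes did not pass as a list, with 11 of 17 positive and a median of 0.11 (camera adjusted p = 0.279). The growth factor receptor Fgfr3 was called over all genes, with 0.59 ± 0.21 in the authors' deposited table, and was the only member to pass adjusted over the list alone. Complement genes did not pass (camera adjusted p = 0.259), and there the median of 0.20 is positive while the test's direction is negative. C4b was called with -0.61 ± 0.21 in the authors' deposited table, and 3 members passed on the negative side adjusted over the list alone. Antigen presentation genes did not pass, with a median of -0.06 (camera adjusted p = 0.244) and 1 member on each side adjusted over the list alone.

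Genes of meningeal fibroblasts, the cells that build the brain's coverings, were positive in 15 of 16 members with a median log2 fold change of 0.87 (camera adjusted p = 4.45e-12). Fmod, Slc22a6, Slc6a13 and Dcn passed over all genes, and 5 members passed adjusted over the list alone. Slc6a13, a GABA and taurine transporter, had a back-calculated 1.19 ± 0.31 and Dcn, the proteoglycan decorin, 1.16 ± 0.31. Choroid plexus genes were positive in 18 of 19 members, with the largest list median, 1.54 (camera adjusted p = 2.99e-06 and 0.0528 with a correlation of 0.2), and standard errors mostly near or above 1. No member passed over all genes and 1, Rdh5, adjusted over the list alone, with 1.45 ± 0.42. The water channel gene Aqp1 had 2.53 ± 1.38. The transthyretin gene Ttr, looked at after its value was seen as the most abundant member, had 1.72 ± 1.22. Ependymal and cilia genes went the other way, negative in 13 of 15 members with a median of -0.40 (camera adjusted p = 0.00086 and 0.155 with a correlation of 0.2), none over all genes and 3 adjusted over the list alone. Ccdc153 had -1.24 ± 0.35 and Meig1 -1.09 ± 0.35.

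Red blood cell genes were negative in all 7 tested members, with a median log2 fold change of -0.60 (camera adjusted p = 6.8e-06). No member passed over all genes and 2 passed adjusted over the list alone, Hbb-bs with -0.70 ± 0.20 and Hbb-bt with -0.60 ± 0.19. The globin genes are close copies of one another, so reads may have been split between them, and their values are uncertain for that reason. Endothelial genes did not pass (camera adjusted p = 0.805); their median was -0.03 while the test's direction was positive. The lipid transporter gene Mfsd2a was called over all genes, with 0.86 ± 0.28 in the authors' deposited table, and passed adjusted over the list alone. Genes of endothelial activation (median 0.28, test direction negative, camera adjusted p = 0.805) and of pericytes and smooth muscle (median -0.11, camera adjusted p = 0.485) did not pass, with no member adjusted over the list alone. Neutrophil genes (median -0.02 with a positive test direction, camera adjusted p = 0.841) and monocyte and macrophage genes (median 0.22, camera adjusted p = 0.336) had no member past either threshold. Of 16 lymphocyte genes 4 were tested, too few for the set test, and 1 passed adjusted over the list alone, Trbc2 of the T cell receptor with 1.52 ± 0.51. Of the 4, 3 were positive and 1 was negative, Trac, also of the T cell receptor, with -1.11 ± 0.65. Mean counts of Trbc2 and Trac are low, 25.2 and 14.6 in the authors' deposited table.

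The list of lymphatic endothelial markers, the cells the treatment is aimed at in the meninges, did not pass (10 tested members, 6 positive, median 0.35, camera adjusted p = 0.244). The RNA is from hippocampus, so this list cannot show whether the treatment removed lymphatic vessels of the meninges. Reln, which in the brain is made mainly by interneurons and Cajal-Retzius cells, was its called member, with 0.70 ± 0.20 in the authors' deposited table, and passed adjusted over the list alone. Lyve1, looked at after its value was seen, had 0.87 ± 0.51 and a mean of 23.3 normalized counts in the authors' deposited table, and Prox1, also a marker of dentate granule neurons, had -0.29 ± 0.13.

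Neuronal lists differed by cell type and region. Interneuron genes were positive in 13 of 14 members with a median log2 fold change of 0.34 (camera adjusted p = 3.44e-06), none over all genes and 1 adjusted over the list alone, Lamp5 with 0.56 ± 0.17. Lamp5 is also a member of the upper layer cortical list added afterwards. The neuropeptide gene Vip had 0.49 ± 0.21. Granule neuron genes of the dentate gyrus were negative in 10 of 12 members with a median of -0.34 (camera adjusted p = 6.8e-06), none over all genes and 5 adjusted over the list alone, among them Plk5 with -0.71 ± 0.27. CA1 pyramidal genes were split evenly with a median of 0.09 (camera adjusted p = 0.841), and CA3 and CA2 genes were negative in 8 of 12 members with a median of -0.18 (camera adjusted p = 0.0812). Neither list had a member past the threshold adjusted over the list alone. General excitatory neuron genes did not pass, with a median of -0.05 (camera adjusted p = 0.162). With corrected z they passed on the negative side (camera adjusted p = 0.0415). CA3 and CA2 genes passed on that side when tested among all genes with a p (camera adjusted p = 0.0256).

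Markers of cortex and striatum, which lie near the hippocampus, were positive. Cortex genes were positive in 10 of 12 members with a median log2 fold change of 0.26 (camera adjusted p = 0.00359 and 0.18 with a correlation of 0.2), and Cux2, a transcription factor of upper cortical layers, had 0.77 ± 0.22 and was the member that passed adjusted over the list alone. Striatum genes were positive in 9 of 12 members with a median of 0.19 (camera adjusted p = 0.025). This call was lost with a correlation of 0.05 (camera adjusted p = 0.0713) and of 0.2 (0.304). The dopamine receptor gene Drd1 had 1.27 ± 0.41 and passed adjusted over the list alone. Drd1 is also a member of the layer 6b list added afterwards, so its value is not particular to striatum. Thalamus genes were positive in 11 of 12 members with a median of 0.19 (camera adjusted p = 0.0979). This list passed with camera on ranks (adjusted p = 0.049) and with camera among all genes with a p (adjusted p = 0.0476). No member of these 3 lists passed over all genes.

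**Figure D3:**
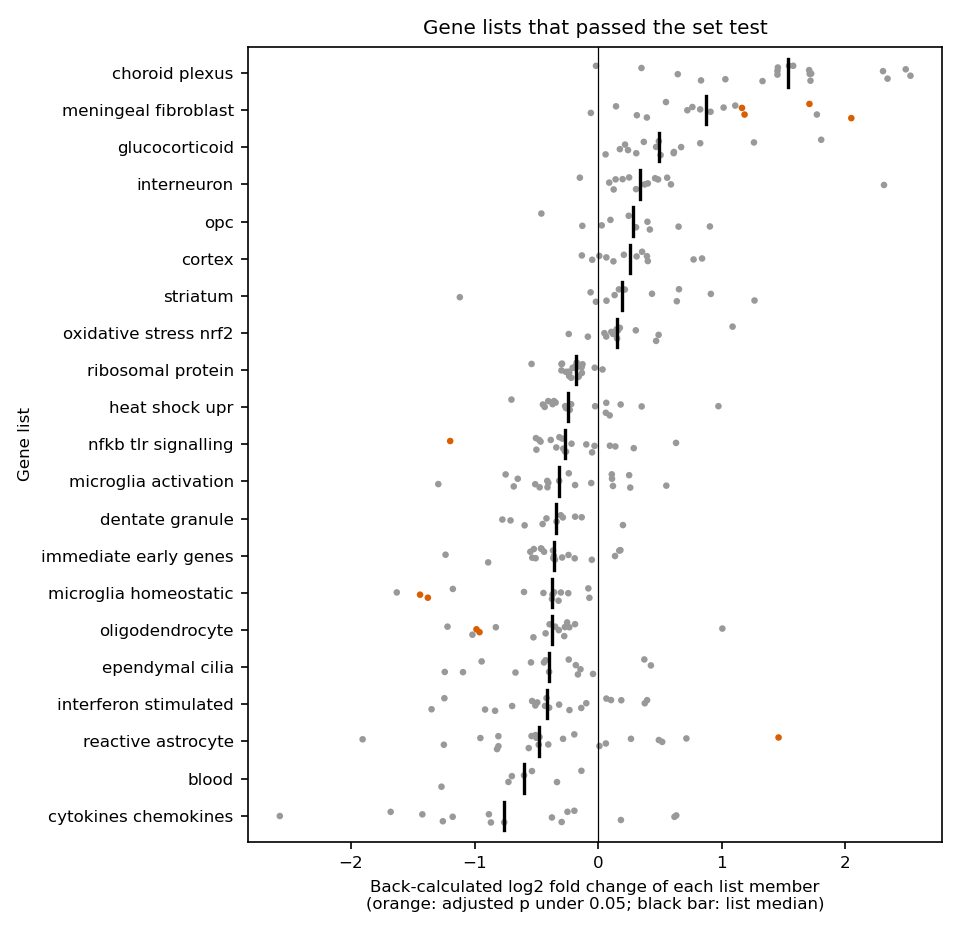
Back-calculated log2 fold change (x axis, log2 units) of each tested member with such a value, in the 21 gene lists that passed the set test (y axis); orange points have an adjusted p under 0.05 over all genes, and black bars mark list medians. Medians run from -0.76 for cytokines and chemokines to 1.54 for choroid plexus genes.

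Among activity and stress genes, immediate early genes, which neurons and glia induce within minutes of stimulation, were negative in 17 of 21 members with a median log2 fold change of -0.36 (camera adjusted p = 9.28e-06 and 0.0939 with a correlation of 0.2). No member passed over all genes and 1 adjusted over the list alone, the nuclear receptor gene Nr4a3 with -0.55 ± 0.18. The neurotrophin gene Bdnf had -0.35 ± 0.17. Heat shock and unfolded protein response genes were negative in 12 of 18 members with a median of -0.24 (camera adjusted p = 0.00757 and 0.304 with a correlation of 0.2). The chaperone genes Pdia4 and Hsph1 had -0.45 ± 0.19 and -0.40 ± 0.18. Genes that glucocorticoids induce were positive in all 15 members with a median of 0.49 (camera adjusted p = 3.5e-07), among them Fkbp5, a co-chaperone of the glucocorticoid receptor, with 0.51 ± 0.22 and Map3k6 with 0.83 ± 0.29. Antioxidant and metal response genes, which share Mt1 and Mt2 with the glucocorticoid list, were positive in 12 of 15 members with a median of 0.15. Their camera adjusted p was 0.0431. It was 0.116 with a correlation of 0.05, 0.415 with 0.2 and 0.0928 over genes with a mean of at least 1 CPM. The glucocorticoid, heat shock and antioxidant lists had no member past the threshold over all genes or adjusted over the list alone.

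Circadian genes (median 0.11, camera adjusted p = 0.0512), p53 and apoptosis genes (median 0.14, camera adjusted p = 0.451) and proliferation genes (median 0.30, camera adjusted p = 0.22) did not pass. Neither did neurogenesis genes (median 0.06 with a negative test direction, camera adjusted p = 0.914), hypoxia and glycolysis genes (median 0.01 with a negative test direction, camera adjusted p = 0.938), matrix remodelling genes (median 0.02, camera adjusted p = 0.388) or amyloid clearance genes (median -0.08, camera adjusted p = 0.451). Adjusted over the list alone, Hopx of the neurogenesis list, Ndrg1 of the hypoxia list and Trem2 of the amyloid clearance list passed on the negative side. Timp2 of the matrix list passed on the positive side. Trem2 is the same gene as in the list of microglial activation above, so it is no further result. The circadian list passed on the positive side when tested among all genes with a p (camera adjusted p = 0.0198).

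Ribosomal protein genes showed a small negative shift in 21 of 22 members, with a median log2 fold change of -0.18 (camera adjusted p = 2.02e-05 and 0.106 with a correlation of 0.2) and no member past either threshold. Mitochondrially encoded genes made up 10.8% of the summed mean counts and did not pass, with a median of 0.02 (camera adjusted p = 0.336), nor did nuclear genes of oxidative phosphorylation (camera adjusted p = 0.843). As a check of the samples, the Y-linked genes Ddx3y and Eif2s3y have means of 730.4 and 844.9 normalized counts in the authors' deposited table and Xist has 1.8, and none of the tested sex-linked genes passed.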

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

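All alternatives were chosen after the data were seen except an adjusted p under 0.1, a minimum of 2-fold on the deposited value and camera on ranks. The counts of called genes, 34 positive and 27 negative, moved by more than 1.5 times in these settings: 61 and 55 at an adjusted p under 0.1, 15 and 8 with at least 2-fold on the deposited value, and 12 and 7 with z divided by its SD. With at least 2-fold on the back-calculated value the negative count moved to 11. The minimum folds and the looser threshold change the counts by construction; the lower counts with the scaled z follow from dividing every z by 1.088. Over all 30477 genes with a p, 45 of the 61 genes stayed under the threshold, over 15211 genes with a mean of at least 1 CPM 59 did, and with z corrected for GC content, length and mean count 49 did. The number of lists passing was 21 and moved to 7 with a preset correlation of 0.2; it ranged from 18 to 24 in the other settings. Which correlation is right was not tested. No list that passed in any setting changed direction. No paired analysis was possible because the files used here hold no value per library and the labels give no matching replicate numbers, only title codes whose meaning is not stated. Leaving out single libraries, other normalizations, filters and count models, an estimated correlation, fry and other splits of the 6 samples were not run for the same reason. The 2.6-fold range of size factors means that the libraries differ in depth, which limits what can be seen in genes with low counts.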

Other observations

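All tests in this part were chosen after the data were seen. For the glucocorticoid list, the outcomes that would count for or against each explanation were written down before those tests were run.

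Lists added after the data were seen describe the called genes further. Layer 6b and subplate genes, neurons under the deepest cortical layer, were positive in 13 of 15 members with a median of 0.31 (camera adjusted p = 5.73e-09). They hold 3 of the called genes, Ccn2, Cplx3 and Nxph3, and without them the adjusted p was 0.00954. Layer 5 and 6 genes (median 0.34, adjusted p = 0.000667) and upper layer genes (median 0.24, adjusted p = 0.000667) were positive as well, while subiculum genes (0.0796) and Cajal-Retzius genes (0.0565) did not pass. A wider oligodendrocyte list was negative in 30 of 32 members with a median of -0.60 and 8 called genes (adjusted p = 2.23e-31), and a wider microglia list in 25 of 30 members with a median of -0.40 and 3 called genes (adjusted p = 1.11e-16). These lists were written with the called genes in view, so their adjusted p is not independent evidence. Without the called genes the camera adjusted p of the wider lists was 3.19e-16 and 3.29e-10. These values are not independent evidence either, since the other genes had also been seen when the lists were written.

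The called genes Itgam, Gatm, Tmem88b, Fa2h and Prr5l carry deposited log2 fold changes between -0.01 and -0.02 in the authors' deposited table, so a reader who ranks genes by fold change would miss them. They may have been left at a lower peak near 0 when the fold changes were shrunken. For 5 of the 5 genes the back-calculated likelihood and prior give a higher peak elsewhere, at -1.30 for Itgam and -0.62 for Gatm. The large z of called genes favours such a peak under the assumed prior, so this count is weak evidence of where the shrinkage stopped. Changes that are truly this small are argued against, since they would need standard errors of at most 0.00556 to reach their z, and the smallest among the other 56 called genes is 0.142. The error derived from the deposited error and the assumed prior, without the p-value, was 0.94 times the back-calculated one (median over 30 genes near 0 with z above 3 in size). Of the 1248 genes with an unadjusted p under 0.05 and a back-calculated value, 1000 also have a deposited value within 0.03 of 0; whether a higher peak lies elsewhere was examined for the called genes only.

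Negative oligodendrocyte and microglia lists came with positive meningeal, choroid plexus and cortical lists, which could come from the makeup of the tissue pieces or from regulation within cells. A smaller share of oligodendrocytes that lowers all their transcripts alike is argued against by the spread of the 16 members (Cochran's Q, chi-square p = 0.00116, and 0.00754 with Q divided by the variance of z; 0.0076 and 0.03 without Enpp2 and Trf, which the choroid plexus also makes). The same chi-square test over 14 homeostatic microglia genes gave p = 0.000416, and 0.00309 with Q divided in that way, which argues against a uniform smaller share of microglia. Members of the meningeal list also differed by more than their errors (chi-square p = 9.28e-06), which goes against a uniform shift only. No such spread was detected for choroid plexus (chi-square p = 0.821) or dentate granule genes (chi-square p = 0.417). Errors of choroid plexus genes are large, so a spread there could have been missed. The tests on the 2 glial lists also go against a uniform shift only. A smaller share of oligodendrocytes or microglia that lowers their genes unequally therefore stays open. A different share of meninges, choroid plexus or dentate gyrus stays open too. So do shifts between subtypes of glia, transcripts made by other cells and regulation within cells, with the treatment as an untested biological cause. More cortex and less hippocampus in the pieces cannot be told apart from regulation. In the main test 1 of the 3 hippocampal neuron lists, dentate granule, passed on the negative side. CA3 and CA2 genes did so only when tested among all genes with a p (camera adjusted p = 0.0256), and CA1 genes did not pass. Several CA1 markers are also made in cortex.

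All 15 glucocorticoid-induced genes were positive. Overlap with the other lists is argued against, since the 10 members in no other list gave an adjusted p of 1.71e-06 by camera, which for a single list equals the unadjusted one. With a preset correlation of 0.2 the adjusted p was 0.0211, under the bound of 0.05 written down as counting against this explanation. That bound was too weak, since 0.2 is an assumed value: genes under a common hormone could be correlated more strongly than that, and the correlation could not be estimated without values per library, so correlated members stay open as the source of the small p. A response to the treatment, to handling or to the hour of collection was not tested.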
